A study of Homo sapiens with 8 samples.

How the data were processed

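RNA was measured by poly(A)-selected sequencing in LN229, an established human glioblastoma cell line. Per the labels' protocols, cells in medium with 10% serum were seeded 24 h before a single exposure to γ-rays, received fresh medium afterwards, and were collected 12 h or 7 d later beside unirradiated cultures. The dose is not given in the sources used here. Libraries were made from 100 ng of total RNA with a directional kit and read in single-end mode over 50 cycles, per the labels. The design holds 4 groups of 2 libraries, 8 in all. The labels do not say whether the libraries of a group came from separate cultures. The p-values of single genes thus measure only the spread between these samples, which may be technical.

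The values are log2 expression values deposited by the authors, 1 per gene and library, for 14463 genes. Per the file headers, reads were summarised over RefSeq genes, columns were normalized, and genes were kept where at least 1 of the 8 samples had a raw value of 20 or more. The genome build was GRCh38 per the submitters' processing notes. The aligner, the counting program, its use of strand and the normalization method are not given in the sources used here. Each gene's deposited log2 values were found to be centred on its median over the 8 samples, and in 941 genes at least 2 libraries shared the lowest value (tolerance 2e-06 in log2). Those shared values fitted a floor at a normalized value of 1 before the logarithm. With that floor and 1 factor per library, the rebuilt number of samples at 20 or more raw reads matched the number the authors deposited for 939 of the 941 genes (99.8%).

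This form of the table limits what can be read from it. Centring removes the level of a gene, so genes cannot be ranked by expression, and changes of genes near the floor are understated. Of the values above the floor in those 941 genes, 72.2% came out as whole reads (tolerance 0.01 reads), which may reflect reads assigned to genes in part and was not tested, and no count test was run. The factors give relative depth only. Relative to the shallowest library (irradiated 12 h replicate 2, set to 1), depth was 1.85 and 1.01 in unirradiated 12 h cells, 1.28 in the other irradiated 12 h library, 1.13 and 1.06 in unirradiated 7 d cells, and 1.55 and 2.23 in irradiated 7 d cells. Total reads per library are unknown. Genes that overlap another gene, lie antisense to one, or share sequence with near copies (histones, HLA and IFITM genes, ribosomal proteins) carry uncertain values. Among the named genes such overlaps, where not given beside the value, concern RB1, CCND1, GLB1, IL6, LOXL2, FANCD2, HIST2H2AB, CKMT2, NDRG2 and RPL7.

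All 8 libraries entered a linear model with 4 groups in limma 3.58.1 (R 4.3.3), fitted to the deposited log2 values without a further pseudocount. Genes at the floor in more than 6 libraries were left out (30 genes), which left 14433. The planned trend of the prior variance with expression could not be used on centred values. The prior variance was instead estimated separately by the number of samples with a raw value of 20 or more, which the authors deposited for each gene. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested in a contrast and a threshold of 0.05. The contrasts were irradiated minus unirradiated at 12 h, the same at 7 d, the difference between these effects, and unirradiated 7 d minus unirradiated 12 h. On simulated data with the same 14433 genes, the 12 h contrast recovered 40% of 100 genes changed by 1 on the log2 scale and 95% of 100 changed by 2, with 10 false calls among 145. For the 7 d contrast the shares were 22% and 97%, with 7 false calls among 126. The changed genes were drawn only from those with 20 raw reads in all 8 samples. Simulated noise was independent between genes and equal in all groups, whereas the real unirradiated 12 h pair varied most. The shares may therefore be too high for the 12 h contrast, and they do not cover genes with few reads.

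Planned choices were fixed before the data were examined, among them 26 gene lists, 23 genes to be reported whatever their result, and the rule for other named genes. That rule took the 10 largest increases and 10 largest decreases per irradiation contrast (5 for the other contrasts) among protein-coding genes past the threshold with separated groups, and up to 4 members per list. Its requirement on mean level was replaced by a raw value of 20 or more in at least 2 libraries. Of the fixed genes, CDKN2A, CDKN2B, CDKN2C and GDF15 were not analysed here, and some genes that the rule or the fixed set names are not reported here. The lists covered TAZ/YAP targets, Hippo pathway components, p53 targets, senescence-associated secretory factors, DNA replication, mitosis, homologous recombination and Fanconi anaemia, non-homologous end joining, the type I interferon response, NF-kB targets, immediate-early genes, cholesterol biosynthesis, lysosome, extracellular matrix, hypoxia and glycolysis, the unfolded protein and integrated stress response, ribosomal proteins, replication-dependent histones, cilium and axoneme, and markers of astrocytes, oligodendrocyte lineage, neurons, endothelium, leukocytes and fibroblasts or pericytes. Mitochondrially encoded genes were not analysed here. The other 25 lists, each with at least 5 measured members, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 100 pairs of list and contrast. Camera compares a list with the other genes. At a preset correlation its p-values rest on the spread over genes, so very small ones do not measure the spread between libraries. Each was repeated with a correlation estimated from the residuals and with fry, a rotation test that does not compare a list with other genes. The setting with an estimated correlation raised adjusted p even for lists with estimates near the preset. A call lost there need not reflect correlated members. It may do so where the estimate lay far above the preset, as for ribosomal proteins (0.86) and histones (0.80).

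Gene positions are from GENCODE release 29 on GRCh38, matched by Ensembl identifier for 13904 genes, and gene types were matched by Entrez identifier for 14422. Alternatives were quantile normalization and median scaling of the deposited values, no filter, a single prior variance, the replicate number as a block, only the libraries of a contrast, an added fold threshold of 2, and each library left out in turn. A further 4 were chosen after seeing the data: a raw value of 20 in at least 2 or in all 8 libraries, 1 weight per group, and removal of histone genes. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.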

Results

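Gene expression was measured in 8 libraries of LN229 glioblastoma cells, 2 each from unirradiated and irradiated cells at 12 h and at 7 d. The question set by the series is how radiation-induced growth arrest and senescence of glioma cells relate to TAZ (gene WWTR1), a transcriptional coactivator of the Hippo pathway. Values are the authors' log2 expression values centred per gene, so changes are log2 differences between group means (n = 2 libraries per group). Total reads per library are unknown, and relative depth ranged from 1 in the shallowest library to 2.23 in the deepest, irradiated 7 d replicate 2. The first principal component held 38.02% of the variance and placed the irradiated 7 d libraries at 38.7 and 41.7, the unirradiated 7 d libraries at 5.03 and 1.52, and the 12 h libraries between -18.0 and -28.0. The unirradiated 12 h libraries differed most from each other, with an SD of the difference of 0.563 over 10691 genes, against 0.421 in irradiated 12 h cells, 0.382 in unirradiated 7 d cells and 0.378 in irradiated 7 d cells.

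At 12 h after irradiation, p53 target genes were higher and mitotic genes lower as groups, while no single gene passed the threshold over all genes. With an estimated correlation the p53 list still passed and the mitosis list did not (0.0634). All 30 measured p53 targets had positive log2 changes, with a median of 0.88. Adjusted over the list alone 17 rose and 0 fell, against 0 over all genes. Among the 17 were the cell cycle inhibitor CDKN1A (log2 1.47, SE 0.21), the pro-apoptotic gene BBC3 (3.01, SE 1.10), PHLDA3 (1.75, SE 0.30), TP53INP1 (1.72, SE 0.60), which overlaps NDUFAF6 on the other strand, and the p53 inhibitor MDM2 (0.67, SE 0.19). The list passed in camera (Benjamini-Hochberg adjusted p = 7.85e-19), also with adjusted p = 0.0254 with an estimated correlation.

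Of 45 genes of G2 and mitosis, 41 had negative changes at 12 h, with a median log2 change of -0.45. Adjusted over the list alone 11 fell and 0 rose, against 0 over all genes. These included the kinesins KIF20A (log2 -1.34, SE 0.19) and KIF18A (-1.43, SE 0.27), cyclin CCNB2 (-1.23, SE 0.28) and the centrosomal kinase NEK2 (-1.20, SE 0.25). KIF20A overlaps CDC23 and BRD8 on the other strand, and KIF18A overlaps METTL15. The mitosis list had a camera Benjamini-Hochberg adjusted p = 1.73e-14 at the preset correlation, and fry gave 0.00382. The proliferation marker MKI67 had a log2 change of -0.22 (SE 0.19) and did not pass.

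TAZ and its targets showed no detectable change at 12 h. WWTR1 had a log2 change of -0.07 (95% interval -0.46 to 0.32), CTGF one of -0.09 (SE 0.18), CYR61 one of -0.23 (SE 0.19) and ANKRD1 one of -0.48 (SE 0.25). The 22 TAZ/YAP targets had a median of -0.08 and 0 passed either adjustment (camera Benjamini-Hochberg adjusted p = 0.129). Type I interferon genes had a median of 0.24 over 39 members, with 0 members past the threshold over all genes or adjusted over the list alone. Their camera Benjamini-Hochberg adjusted p was 0.0271, with adjusted p = 0.465 with an estimated correlation. That call also ended with fry (0.271), under quantile normalization (0.134), and without unirradiated 12 h replicate 2 (0.308) or irradiated 12 h replicate 1 (0.0574) or 2 (0.0719). Adjusted over their lists alone, 1 of 10 fibroblast and pericyte markers (ACTA2, smooth muscle actin, 2.83-fold, SE 0.20 on the log2 scale, overlapping FAS), 1 of 23 NF-kB targets (PTGS2, 1.89, SE 0.41) and 1 of 24 immediate-early genes (ATF3, 1.14, SE 0.22) rose and 0 fell, against 0 over all genes in each. Those lists did not pass (camera Benjamini-Hochberg adjusted p = 0.122, 0.106 and 0.927), although NF-kB targets did without irradiated 12 h replicate 1 (0.0277) and fibroblast and pericyte markers did with fry (0.0350).

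Over all genes at 12 h, limma called 0 of 14433 at a Benjamini-Hochberg adjusted p under 0.05. The smallest adjusted p in limma was 0.153, and 1073 genes (7.43%) had an unadjusted p under 0.05, 571 of them higher and 502 lower. The count depended on the unirradiated 12 h pair: 8 genes without its replicate 1, 35 without its replicate 2, and 2 genes with a single prior variance in limma. Without unirradiated 12 h replicate 2, histone genes were higher (camera adjusted p = 1.32e-12) and ribosomal protein genes lower (0.00945), both opposite in sign to all libraries together (0.130 and 0.229). Without its replicate 1 they passed in the opposite directions (8.80e-24 and 2.90e-06), and ribosomal proteins also passed without irradiated 12 h replicate 2 (0.0396).

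**Figure D1:**
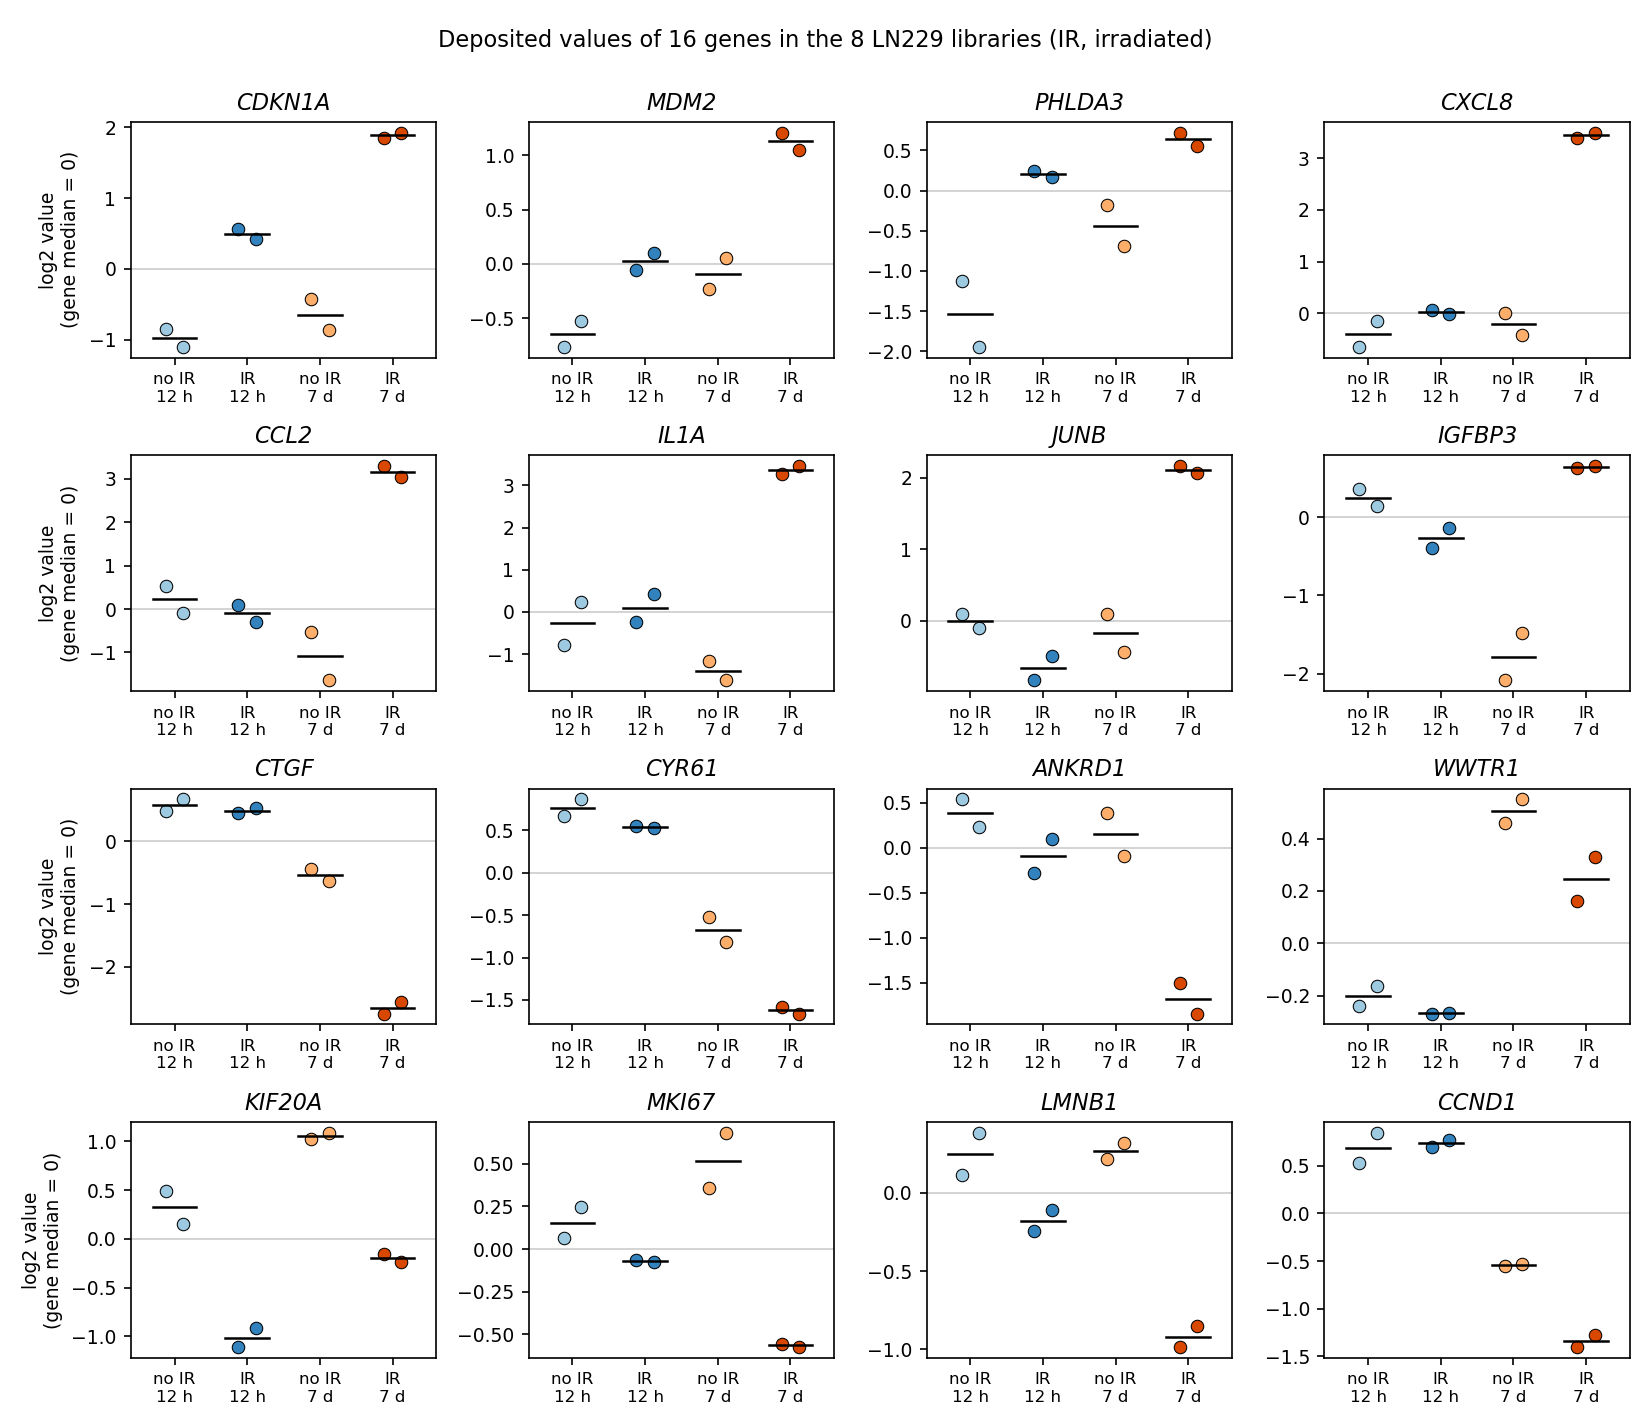
Deposited log2 expression values, centred on each gene's median over the 8 libraries, for 16 genes in each library, by group. CXCL8 lay far above the other groups in both irradiated 7 d libraries (group mean 3.44), CTGF far below (-2.65), and CDKN1A was higher in irradiated than unirradiated cells at both times (0.50 against -0.98 at 12 h and 1.89 against -0.65 at 7 d).

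NF-kB targets, a set of inflammatory signalling genes, were raised in irradiated cells at 7 d. Of 23 NF-kB targets, 17 rose and 0 fell over all genes (22 and 0 adjusted over the list alone), and the list's median log2 change was 2.89. The chemokine CXCL8 rose by 3.65 (SE 0.23), from a deposited value of -0.21 ± 0.30 in unirradiated 7 d cells to 3.44 ± 0.07 in irradiated 7 d cells (SD, n = 2). Its limma Benjamini-Hochberg adjusted p was 0.00277, and its change was 2.32 under quantile normalization. CCL2 rose by 4.25 (SE 0.38), the cytokine IL1B by 6.09 (SE 0.97) and CXCL3 by 4.88 (SE 0.98). IL1B reached 20 raw reads in 3 libraries and CXCL3 in 2. IL6 had a log2 change of 4.75 (SE 1.37) and did not pass (limma Benjamini-Hochberg adjusted p = 0.0799). The NF-kB list passed in camera (Benjamini-Hochberg adjusted p = 7.85e-19), also with adjusted p = 0.0430 with an estimated correlation.

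Senescence-associated secretory factors were higher in irradiated than in unirradiated cells at 7 d as a group. The list also fell with culture time in unirradiated cells (median -0.59). Its 27 members outside the NF-kB list lay a median of 0.19 above the 12 h libraries in irradiated 7 d cells (SE 0.22, bootstrapped over genes). Their change from the 7 d controls was 1.15. Of 36 members, 16 rose and 0 fell over all genes, and 28 rose and 1 fell adjusted over the list alone, with a median log2 change of 1.30. They included the cytokine IL1A (4.76, SE 0.62) and the growth factor-binding protein IGFBP3 (2.43, SE 0.24). SERPINB2 also rose and was listed at the floor in both unirradiated 7 d libraries, so no fold is given. The list passed in camera (Benjamini-Hochberg adjusted p = 5.11e-16), also with adjusted p = 0.0254 with an estimated correlation. Among the 5 measured leukocyte markers, CD68 (2.56, SE 0.35) and CD74 (1.06, SE 0.19) rose at 7 d and 0 fell (3 and 0 adjusted over the list alone). CD68 overlaps a gene on the other strand. The leukocyte list had a camera Benjamini-Hochberg adjusted p = 0.00200, and adjusted p = 0.184 with an estimated correlation.

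All 39 interferon-stimulated genes had a positive change at 7 d, with a median of 1.93 on the log2 scale. Their list passed in camera (Benjamini-Hochberg adjusted p = 9.05e-16) and with fry (0.00194), but not with an estimated correlation (0.0634). Over all genes 6 rose and 0 fell, and adjusted over the list alone 27 rose and 0 fell. ISG15, a ubiquitin-like modifier, rose by 6.32 (SE 0.97), IFI6 by 3.95 (SE 0.81), the membrane protein IFITM3 by 2.14 (SE 0.31) and the transcription factor IRF1 by 2.01 (SE 0.31). Under quantile normalization IFI6 changed by 2.60 and lost its call (limma Benjamini-Hochberg adjusted p = 0.0787), and IRF1 changed by 1.32. Others among the 10 largest increases were the iron-binding protein LCN2 (7.61, SE 1.04), the cytokine IL32 (6.87, SE 0.73), complement C3 (6.50, SE 1.43), which overlaps GPR108, and the ubiquitin-like gene UBD (5.95, SE 0.93), which overlaps GABBR1. FDCSP and C8orf4 rose and were listed at the floor in both unirradiated 7 d libraries.

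p53 targets were also higher at 7 d, and genes of mitosis and DNA replication were lower, though neither of the latter lists passed with an estimated correlation (0.0537 and 0.0902). Of 30 p53 targets, 10 rose and 0 fell over all genes (22 and 0 adjusted over the list alone), with a median log2 change of 1.11. CDKN1A rose by 2.53 (SE 0.21, limma Benjamini-Hochberg adjusted p = 0.00396), the death receptor FAS by 2.09 (SE 0.37), GADD45A by 2.04 (SE 0.42), the anti-proliferative gene BTG2 by 2.00 (SE 0.36) and MDM2 by 1.22 (SE 0.19). FAS overlaps ACTA2 on the other strand, and MDM2 overlaps CPM. The p53 list passed in camera (Benjamini-Hochberg adjusted p = 1.31e-10), also with adjusted p = 0.0430 with an estimated correlation. RB1 changed by -0.08 (SE 0.20) and CDKN1B by 0.19 (SE 0.25), and neither passed.

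Of 45 mitotic genes, 16 fell and 0 rose at 7 d over all genes (34 and 0 adjusted over the list alone), with a median of -0.78. ASPM changed by -1.58 (SE 0.25), NEK2 by -1.43 (SE 0.25), PLK4 by -1.35 (SE 0.19), CENPE by -1.30 (SE 0.22) and MKI67 by -1.08 (SE 0.19). The mitosis list had a camera Benjamini-Hochberg adjusted p = 9.13e-18, and adjusted p = 0.0537 with an estimated correlation, while fry gave 0.00116. Of 44 DNA replication genes, 4 fell and 0 rose over all genes (21 and 0 adjusted over the list alone), with a median of -0.54; they were POLE2 (-1.81, SE 0.32), UHRF1 (-1.16, SE 0.24), MCM10 (-1.07, SE 0.16) and CLSPN (-0.98, SE 0.19). The replication list had a camera Benjamini-Hochberg adjusted p = 1.68e-11, and adjusted p = 0.0902 with an estimated correlation, while fry gave 0.00495. Of 35 homologous recombination and Fanconi anaemia genes, DNA2 (-1.34, SE 0.24), RAD51D (-1.03, SE 0.21) and FANCD2 (-0.94, SE 0.17) fell and 0 rose (9 and 0 adjusted over the list alone; median -0.51; camera Benjamini-Hochberg adjusted p = 3.3e-07, and adjusted p = 0.116 with an estimated correlation). The nuclear lamina gene LMNB1 fell by 1.19 on the log2 scale (SE 0.18), while HMGB1 (-0.93, SE 0.20), HMGB2 (-0.65, SE 0.23) and CCND1 (-0.80, SE 0.18) did not pass. Replication-dependent histones had a median of -1.81 over 53 genes, with 3 fallen and 0 risen over all genes (43 and 0 adjusted over the list alone). HIST1H3C (-2.14, SE 0.39), HIST2H2AB (-1.92, SE 0.36) and HIST1H2BE (-1.90, SE 0.31) were those 3, and histone genes share reads with near copies. The histone list had a camera Benjamini-Hochberg adjusted p = 5e-17, and adjusted p = 0.457 with an estimated correlation; fry gave 0.119.

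**Figure D2:**
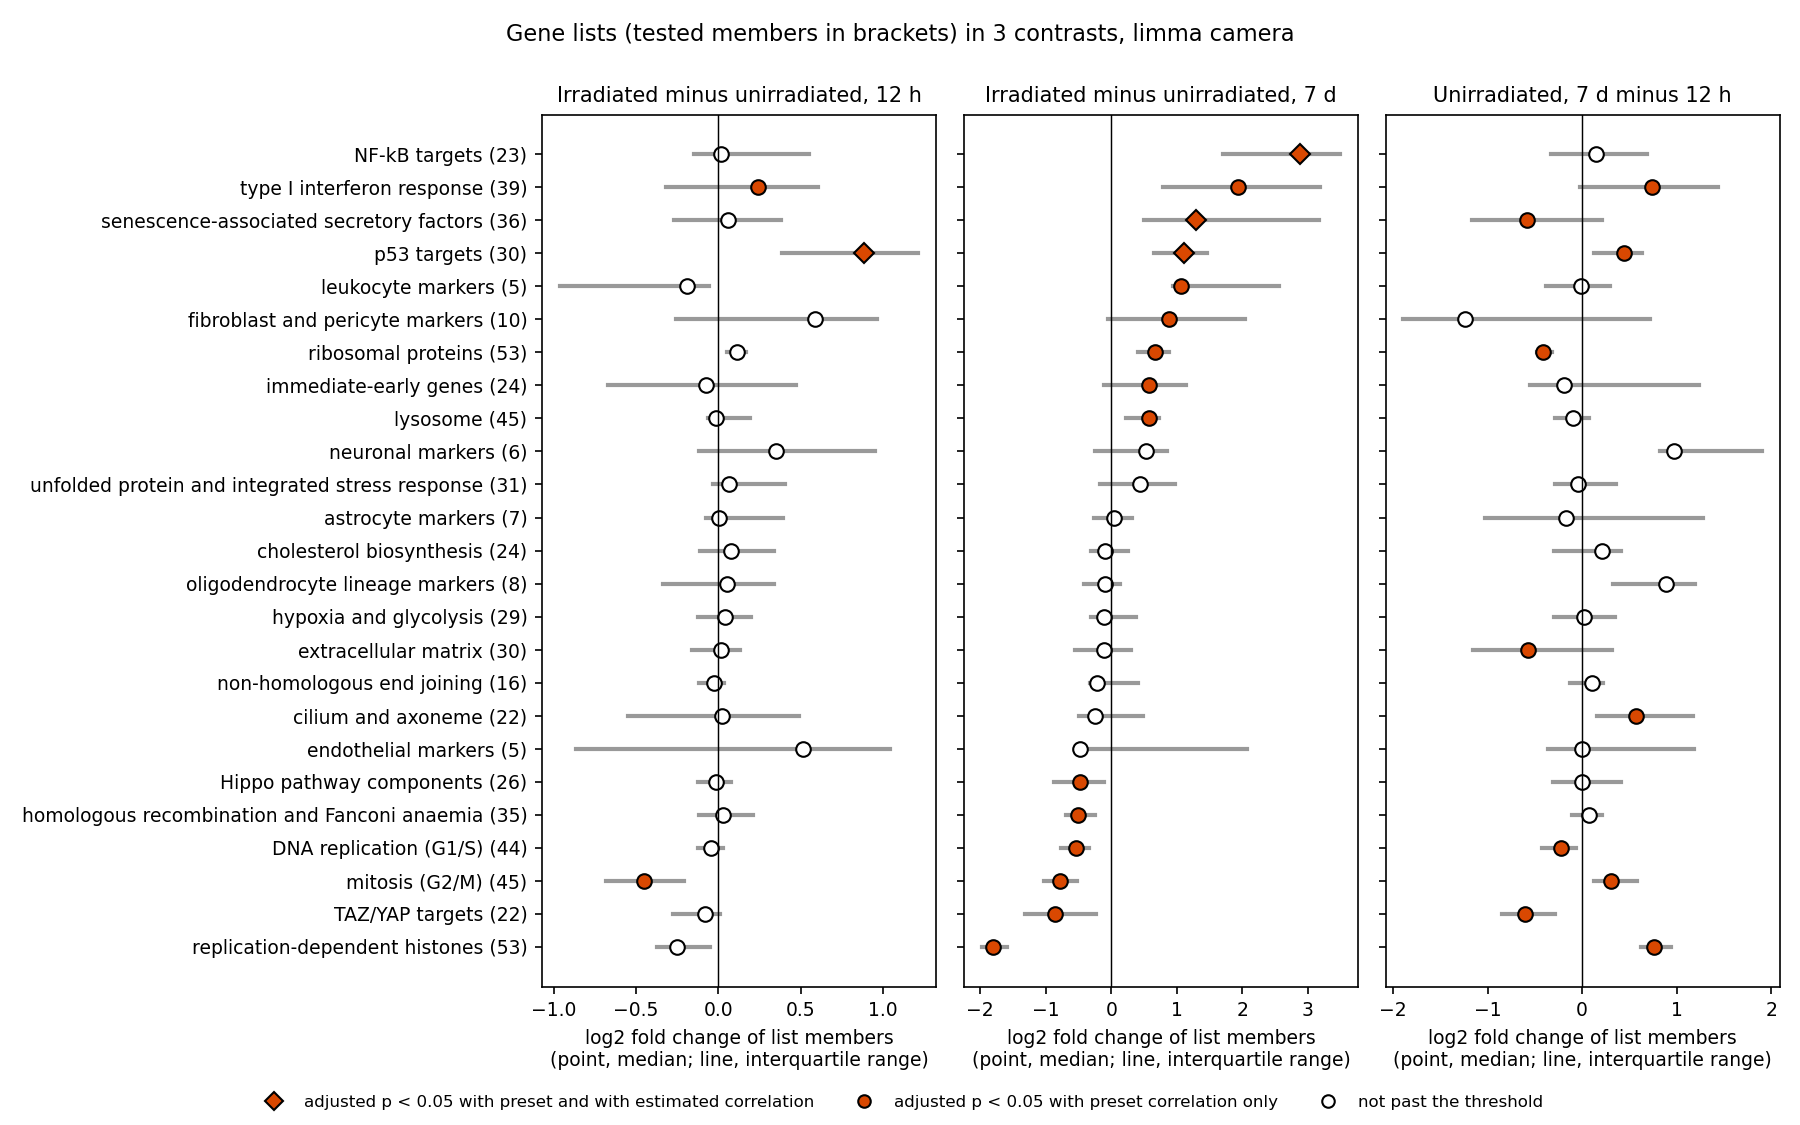
Median log2 change (point) and interquartile range (bar) over the members of each gene list for irradiation at 12 h, irradiation at 7 d, and unirradiated 7 d minus unirradiated 12 h. Diamonds mark lists past the threshold also with an estimated correlation: p53 targets at 12 h (median 0.88), and NF-kB targets (2.89), secretory factors (1.30) and p53 targets (1.11) at 7 d.

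TAZ/YAP target genes were lower in irradiated cells at 7 d, while the TAZ transcript itself was not detectably changed. The list of targets passed in camera (Benjamini-Hochberg adjusted p = 2.03e-06) and with fry (0.00430), but not with an estimated correlation (0.184). Of 22 targets, 9 fell and 2 rose over all genes (14 and 3 adjusted over the list alone), with a median log2 change of -0.86. CTGF (chromosome 6, 131948176 to 131951373, minus strand, GRCh38), a secreted matrix protein, changed by -2.11 (SE 0.18, limma Benjamini-Hochberg adjusted p = 0.00396), from -0.54 ± 0.14 to -2.65 ± 0.13 (SD, n = 2). ANKRD1 changed by -1.82 (SE 0.25), AMOTL2 by -1.30 (SE 0.17) and CYR61 by -0.95 (SE 0.19). The 2 that rose were IGFBP3 and GADD45A, which are also on the secretory and p53 lists. WWTR1 (chromosome 3, 149517235 to 149736714, minus strand) changed by -0.26 (95% interval -0.65 to 0.13, limma Benjamini-Hochberg adjusted p = 0.417), and its paralog YAP1 by -0.11 (SE 0.24). Of 26 Hippo pathway components, 6 fell and 0 rose (9 and 1 adjusted over the list alone), with a median of -0.48. AMOT (-1.23, SE 0.20), PTPN14 (-1.21, SE 0.22) and the tumour suppressor NF2 (-1.19, SE 0.22) were among them. AMOTL2, PTPN14 and LATS2 belong to both lists. The Hippo list had a camera Benjamini-Hochberg adjusted p = 2.41e-05, and adjusted p = 0.287 with an estimated correlation, while fry gave 0.0172.

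Lysosomal genes had a median of 0.57 at 7 d over 45 genes. Their list passed in camera (Benjamini-Hochberg adjusted p = 3.89e-07) and with fry (0.00949), but not with an estimated correlation (0.151). Cathepsin CTSS (3.70, SE 0.79), TPP1 (1.10, SE 0.19), SMPD1 (1.02, SE 0.18) and PSAP (0.99, SE 0.17) rose and 0 fell (8 and 0 adjusted over the list alone). GLB1, which encodes lysosomal beta-galactosidase, changed by -0.20 (SE 0.17) and did not pass. Of 24 immediate-early genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone; median 0.58), among them ATF3 (2.80, SE 0.22), JUNB (2.28, SE 0.23), which overlaps HOOK2, and EGR1 (-1.35, SE 0.21). JUNB changed by 1.45 under quantile normalization. Their camera Benjamini-Hochberg adjusted p was 0.00632, with adjusted p = 0.269 with an estimated correlation, and the call ended without irradiated 7 d replicate 2 (0.0892). The stress-response gene DDIT3 rose by 1.96 (SE 0.30) and overlaps MARS; 5 of 31 genes of the unfolded protein and integrated stress response rose and 0 fell (7 and 1 adjusted over the list alone), but the list did not pass (median 0.44, camera Benjamini-Hochberg adjusted p = 0.0711), although it did with fry (0.0403) and among genes with 20 raw reads in all 8 libraries (0.0156). ACTA2 rose by 2.18 (SE 0.20), the 1 gene of 10 fibroblast and pericyte markers to pass over all genes, with 0 fallen (4 and 1 adjusted over the list alone; median 0.88). That list passed narrowly (camera Benjamini-Hochberg adjusted p = 0.0466), with adjusted p = 0.262 with an estimated correlation, and ended without unirradiated 12 h replicate 1 (0.0833) or 2 (0.0796), either irradiated 12 h library (0.0523), unirradiated 7 d replicate 1 (0.126) or irradiated 7 d replicate 2 (0.0627). It also ended with 1 weight per group (0.0663) or the replicate number as a block (0.0628). Ribosomal protein genes had a median of 0.67 over 53 members, with 0 past the threshold over all genes or adjusted over the list alone. Their camera Benjamini-Hochberg adjusted p was 1.19e-09, with adjusted p = 0.634 with an estimated correlation, and fry gave 0.244.

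The remaining lists did not pass at 7 d. The matrix gene THBS1 (-1.41, SE 0.17), which overlaps FSIP1, COL8A1 (-0.96, SE 0.19) and LOXL2 (-0.85, SE 0.17) fell among 30 extracellular matrix genes and 0 rose (5 fell and 1 rose adjusted over the list alone; median -0.12, camera Benjamini-Hochberg adjusted p = 0.143, and 0.0171 without unirradiated 7 d replicate 1). The kinase PDK1 (-1.41, SE 0.20) was the 1 gene of 29 on the hypoxia and glycolysis list to fall, and 0 rose (also 1 and 0 adjusted over the list alone; median -0.11, mean 0.07, camera Benjamini-Hochberg adjusted p = 0.537). TUBB3 rose by 0.91 (SE 0.19) among 6 neuronal markers and 0 fell (1 and 0 adjusted over the list alone; median 0.53, camera Benjamini-Hochberg adjusted p = 0.913). Over all genes 0 members passed on the lists for non-homologous end joining (camera Benjamini-Hochberg adjusted p = 0.597), cholesterol biosynthesis (0.551), cilium and axoneme (0.692), oligodendrocyte lineage (0.763), astrocytes (0.971) and endothelium (0.786). Adjusted over the list alone, FABP7 fell among astrocyte markers (-1.23, SE 0.29) and VWF rose among endothelial markers, listed at the floor in both unirradiated 7 d libraries. The other 4 of these lists had 0. The endothelial list had a median of -0.47 and a mean of 0.47, the cilium list a median of -0.25 and a mean of 0.13.

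Over all genes at 7 d, limma called 478 at a Benjamini-Hochberg adjusted p under 0.05, 283 higher and 195 lower, of which 258 and 136 changed at least 2-fold. Besides CTGF and the histones, the 10 largest decreases included FLG (-3.43, SE 0.40), the netrin receptor UNC5C (-2.18, SE 0.21), adenylate kinase AK4 (-2.11, SE 0.20), GPR39 (-1.95, SE 0.35), which overlaps LYPD1, the integrin ITGA9 (-1.92, SE 0.41) and IL12RB1 (-4.62, SE 0.97), which overlaps MAST3. ITGA9 changed by -1.28 without unirradiated 7 d replicate 2. CKMT2, a mitochondrial creatine kinase, fell and was listed at the floor in both irradiated 7 d libraries. Under quantile normalization the split was 220 higher (39.01%) and 344 lower, against 59.2% higher in the deposited scaling, and 359 of the 478 kept their call and direction. The count was 903 without unirradiated 12 h replicate 1 or without its replicate 2, 197 without irradiated 12 h replicate 1 or without its replicate 2, 57 or 23 without unirradiated 7 d replicate 1 or 2, and 33 or 1 without irradiated 7 d replicate 1 or 2; it was 138 with a single prior variance, 1304 with 1 weight per group and 896 in the 4 libraries of the contrast alone.

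The irradiation effect was larger at 7 d than at 12 h for 10 genes, and smaller for 0, in the test of the difference itself. The difference on the log2 scale was 4.57 for CCL2 (SE 0.54), 3.23 for CXCL8 (SE 0.33), 2.94 for IGFBP3 (SE 0.33) and 2.94 for JUNB (SE 0.33). Others were C1QTNF1 (4.03, SE 0.32), TMEM158 (3.78, SE 0.38), GSAP (2.71, SE 0.27), the semaphorin receptor NRP2 (2.60, SE 0.29) and the antigen-presenting HLA-C (2.58, SE 0.26), which shares reads with other HLA genes. GSAP, NRP2 and HLA-C were named after their values were seen. With culture time in unirradiated cells TMEM158 changed by -2.58, IGFBP3 by -2.03, C1QTNF1 by -1.68, CCL2 by -1.31 and HLA-C by -1.08. NRP2 (-0.73), GSAP (-0.69) and JUNB (-0.17) changed less, and CXCL8 went the other way (0.19). Lower 7 d controls may therefore account for part of the difference in the genes that fell. CTGF had a difference of -2.02 (SE 0.26, limma Benjamini-Hochberg adjusted p = 0.0529). NF-kB targets (median 2.74) and secretory factors (1.37) differed between times as lists, with camera Benjamini-Hochberg adjusted p = 4.25e-17 and 6.3e-15, and adjusted p = 0.0430 and 0.0254 with an estimated correlation. Over all genes 2 NF-kB targets and 4 secretory factors had larger effects at 7 d and 0 smaller (18 and 0, and 19 and 1, adjusted over the list alone). p53 targets had a median difference of 0.22, with 0 members past either adjustment (camera Benjamini-Hochberg adjusted p = 0.433). In limma 1968 genes had an unadjusted p under 0.05; the count of 10 became 19 or 159 without unirradiated 12 h replicate 1 or 2, 0 without any 1 of the other 6 libraries, 3 under quantile normalization or with a single prior variance, 19 with 1 weight per group, 4 with the replicate number as a block (3 of them among the 10), and 18 or 20 among genes with 20 raw reads in at least 2 or in all 8 libraries. Of the 10 genes, 3 kept their call under quantile normalization and 0 with a single prior variance. CXCL8 had a difference of 1.96 under quantile normalization.

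Genes called at 7 d had small changes at 12 h, more of them in the same direction than not, though this depended on the unirradiated 12 h pair. Of the 283 genes raised at 7 d, 171 (60.4%, 95% exact binomial interval 54.5 to 66.2) had a positive change at 12 h, with a median of 0.07 against 1.56 at 7 d. Of the 195 lowered genes, 128 (65.6%, 58.5 to 72.3) had a negative change at 12 h, with a median of -0.10 against -1.12. Genes are not independent replicates, so these intervals are too narrow. As sets, both groups moved the same way at 12 h in camera (Benjamini-Hochberg adjusted p = 0.000909 and 0.000650), each with adjusted p = 0.286 with an estimated correlation. Across the 14433 genes the log2 changes at both times had a Pearson r of 0.0885, as a description. It was 0.150 over the 10691 genes with 20 raw reads in all 8 libraries. By limma 0 genes passed at both times, since 0 passed at 12 h (1073 genes there had an unadjusted p under 0.05); the shared count was 6 without unirradiated 12 h replicate 2 and 1 with a single prior variance. Without unirradiated 12 h replicate 2 the share in the same direction was 51.4% among raised and 41.2% among lowered genes. Without its replicate 1 these shares were 67.1% and 76.1%. Over all genes tested, 50.1% had a positive change at 12 h.

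**Figure D3:**
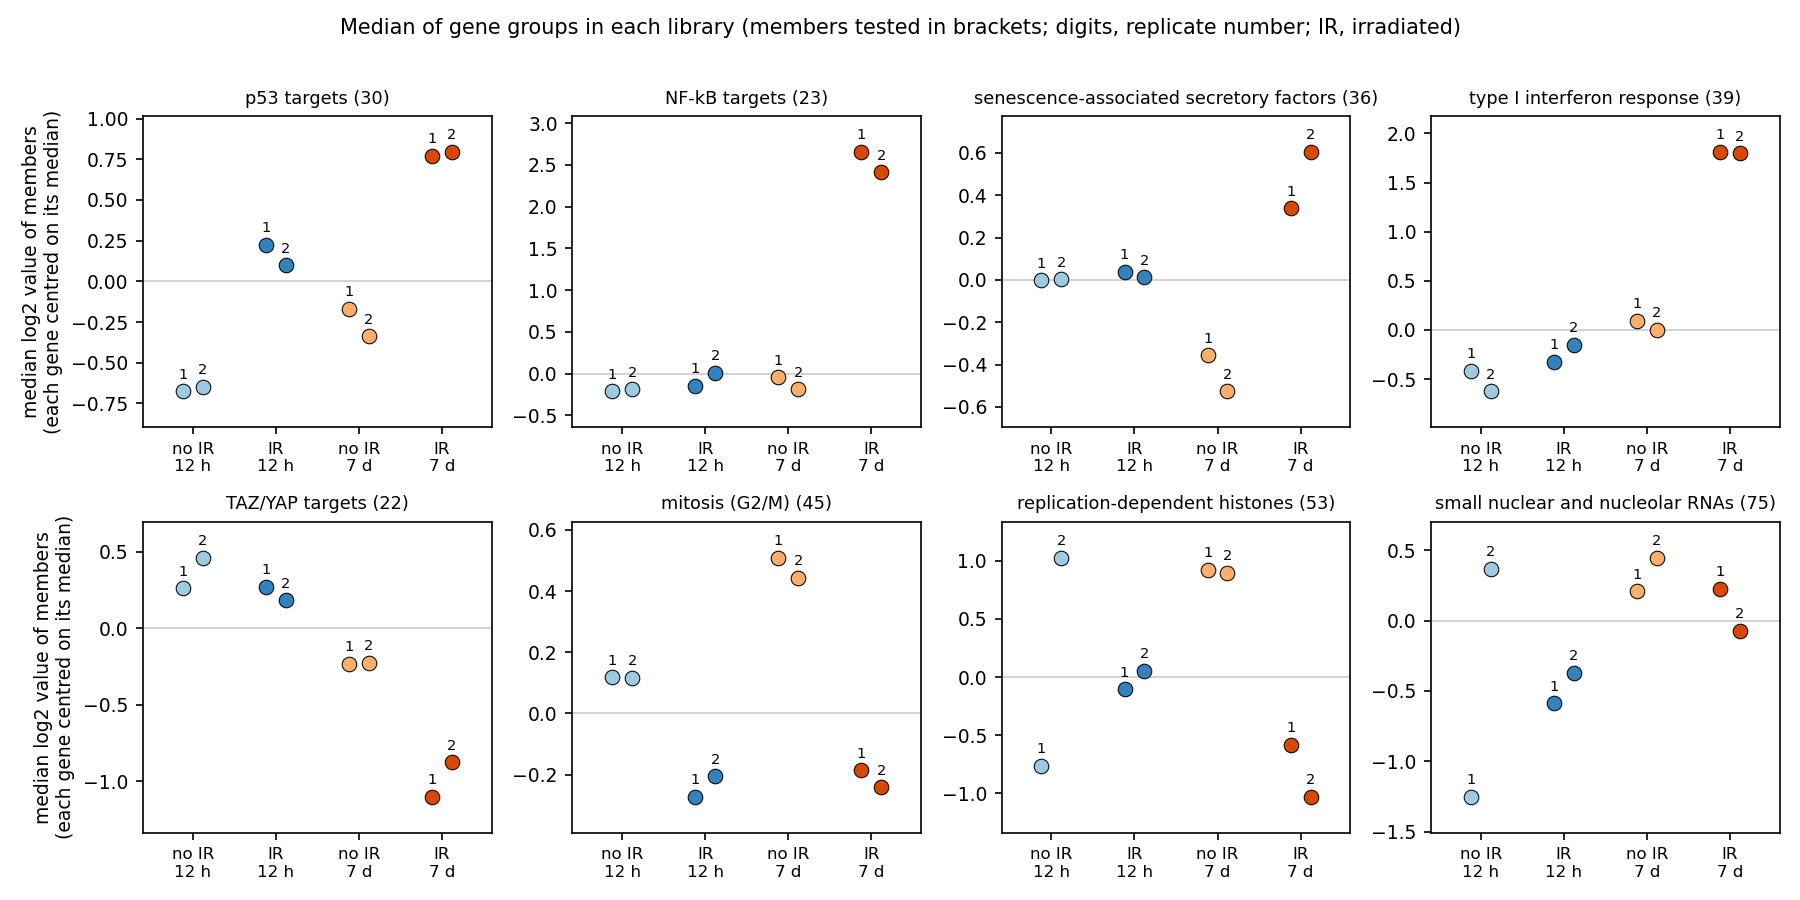
Median deposited log2 value, centred per gene, over the members of 8 gene groups in each library, by group. NF-kB targets lay at 2.66 and 2.41 in the irradiated 7 d libraries and between -0.21 and 0.01 elsewhere, while histones differed within the unirradiated 12 h pair (-0.76 and 1.03).

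Unirradiated cells also changed between 12 h and 7 d of culture, with secreted, matrix and TAZ/YAP target genes lower at 7 d in camera at the preset correlation. None of the lists that passed for culture time did so with an estimated correlation. The interleukin IL11 changed by -2.15 (SE 0.23) and IGFBP3 by -2.03 (SE 0.24), and SERPINB2 fell to the floor in both unirradiated 7 d libraries. Of 36 secretory factors 6 fell and 0 rose (11 and 0 adjusted over the list alone; median -0.59, camera Benjamini-Hochberg adjusted p = 2.41e-05, and adjusted p = 0.0634 with an estimated correlation). Of 30 matrix genes 7 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.57), among them the collagens COL5A1 (-2.23, SE 0.20), COL6A2 (-1.90, SE 0.26) and COL6A1 (-1.69, SE 0.19). The matrix list had a camera Benjamini-Hochberg adjusted p = 6.75e-05, and adjusted p = 0.460 with an estimated correlation. Of 22 TAZ/YAP targets 4 fell and 0 rose (12 and 1 adjusted over the list alone; median -0.61), including tissue factor F3 (-1.89, SE 0.27), CYR61 (-1.43, SE 0.19) and CTGF (-1.11, SE 0.18). Their camera Benjamini-Hochberg adjusted p was 1.71e-07, with adjusted p = 0.166 with an estimated correlation. WWTR1 changed by 0.71 (SE 0.17, limma Benjamini-Hochberg adjusted p = 0.0747), and the cyclin CCND1 by -1.23 (SE 0.18).

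Other large decreases with culture time were those of KRT17 (-6.70, SE 0.98), IL1RL1 (-5.44, SE 0.92), which overlaps IL18R1, and IL32 (-3.73, SE 0.73). PCDH7 rose by 5.68 (SE 0.96), and IL12RB1, TRPM3, ANGPT1 and SOX8 rose from the floor, at which both unirradiated 12 h libraries were listed. Mitotic genes had a median of 0.31 with CENPF (1.03, SE 0.20) the 1 that rose and 0 fallen (5 and 0 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 1.57e-05, and adjusted p = 0.183 with an estimated correlation). Interferon genes had a median of 0.74, with PARP14 (1.06, SE 0.21) the 1 that rose and 0 fallen (6 and 0 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.000410, and adjusted p = 0.268 with an estimated correlation). p53 targets had a median of 0.44, with CCNG1 (1.09, SE 0.17) the 1 that rose and 0 fallen (5 and 1 adjusted over the list alone). Their camera Benjamini-Hochberg adjusted p was 0.00215, with adjusted p = 0.166 with an estimated correlation and 0.126 under quantile normalization. Cilium genes had a median of 0.56, with 1 risen and 0 fallen (3 and 0 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.00520, adjusted p = 0.390 with an estimated correlation, and 0.197 without unirradiated 12 h replicate 1). DNA replication genes (median -0.23, 0 past either adjustment) had a camera Benjamini-Hochberg adjusted p = 6.75e-05, and adjusted p = 0.211 with an estimated correlation. Ribosomal protein genes had a median of -0.42, with RPL7 the 1 that fell and 0 risen (also 1 and 0 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 1.3e-06, and adjusted p = 0.754 with an estimated correlation), a call that ended without unirradiated 12 h replicate 1 (0.212) or unirradiated 7 d replicate 2 (0.132). Histones had a median of 0.75 with 0 past either adjustment (camera Benjamini-Hochberg adjusted p = 2.41e-05, and adjusted p = 0.774 with an estimated correlation), and the direction turned without unirradiated 12 h replicate 1 (0.193). The astrocyte marker NDRG2 rose by 1.44 (SE 0.23), while the lists for oligodendrocyte lineage and astrocytes did not pass (camera Benjamini-Hochberg adjusted p = 0.112 and 0.922), the former passing with fry (0.00714). The 6 neuronal markers had a median of 0.97, with 0 past the threshold over all genes and 4 risen and 1 fallen adjusted over the list alone. Their list did not pass (camera Benjamini-Hochberg adjusted p = 0.0727) but did with fry (0.00122).

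In limma 325 genes differed between unirradiated cells at 7 d and 12 h at a Benjamini-Hochberg adjusted p under 0.05, 166 higher (51.1%) and 159 lower. Under quantile normalization the count was 499, 195 higher (39.1%) and 304 lower. The count was 674 without unirradiated 12 h replicate 2, 6 or 1 without unirradiated 7 d replicate 1 or 2, 146 without irradiated 7 d replicate 1 or without its replicate 2, 166 with a single prior variance, 158 with 1 weight per group, and 0 in the 4 libraries of the contrast alone, against 2742 genes at an unadjusted p under 0.05 in limma over all 8.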

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

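All tests of explanations in this part were chosen after the results were seen. The SEs of their medians are bootstraps over genes (2000 draws). They treat genes as independent and do not measure the spread between libraries, so they are likely too small. The irradiation effect differed between 7 d and 12 h for 10 genes, the test of that difference being what singled them out. Among them were C1QTNF1 (4.03), CCL2 (4.57), TMEM158 (3.78), CXCL8 (3.23), IGFBP3 (2.94), JUNB (2.94), GSAP (2.71), NRP2 (2.60) and HLA-C (2.58), as log2 differences of effects with limma Benjamini-Hochberg adjusted p between 0.0287 and 0.0485. These genes were each higher in both irradiated libraries than in both unirradiated ones at 7 d. All of those named except CXCL8 (0.19) had negative changes with culture time in unirradiated cells, from -0.17 for JUNB to -2.58 for TMEM158. A lower level in the 7 d controls may account for part of their differences.

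As lists, 13 differed between the times in camera, and 2 of them also with an estimated correlation: NF-kB targets (Benjamini-Hochberg adjusted p = 4.25e-17, and 0.0430 with an estimated correlation) and secretory factors (6.3e-15, and 0.0254). The remaining 11 did not hold with an estimated correlation, given second. Higher at 7 d relative to 12 h were the type I interferon response (6.06e-10, 0.117), ribosomal proteins (4.82e-06, 0.754, and 0.0564 without unirradiated 12 h replicate 1), lysosome (8.07e-05, 0.211), leukocyte markers (0.00134, 0.183) and immediate-early genes (0.00659, 0.269, 0.131 without irradiated 7 d replicate 2, and 0.0643 under quantile normalization). Lower were histones (2.36e-12, 0.541), DNA replication (3.77e-08, 0.135), homologous recombination and Fanconi anaemia (9.32e-06, 0.144), TAZ/YAP targets (6.58e-05, 0.244), Hippo pathway components (0.000157, 0.343) and mitosis (0.000350, 0.240). Mitotic genes had library medians of -0.27 and -0.21 in irradiated cells at 12 h and -0.19 and -0.24 at 7 d. In unirradiated cells these were 0.12 and 0.12 at 12 h and 0.51 and 0.44 at 7 d. The mitosis difference thus went with higher 7 d controls, not with a further fall in irradiated cells.

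The rise of NF-kB targets and secretory factors at 7 d was weighed against depth and against a change in the controls. Within groups the 50 genes of both lists changed by a median of 0.062 (SE 0.084) per doubling of depth. Depth would need a change of 2.18 per doubling to give their rise at 7 d, which argues against depth as the whole cause. NF-kB targets in irradiated 7 d cells lay a median of 2.80 (SE 0.50) above the 12 h libraries, close to their change of 2.89 against the 7 d controls, which argues against a lower control as the cause. The 27 secretory factors outside the NF-kB list lay only 0.19 (SE 0.22) above the 12 h libraries, against a change of 1.15 at 7 d, so for these a lower level in the unirradiated 7 d cells may account for much of the difference. An effect of irradiation and one of culture density or age on the 7 d controls stay open for that part, since density was not measured.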

How the results depend on the processing

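The weight per group, the filters on raw values of 20 and the removal of histone genes were chosen after seeing the data. At 12 h the count of genes (0) was 2 with a single prior variance and ranged from 0 to 35 when 1 library was left out. At 7 d (478) it was 138 with a single prior variance, 1304 with 1 weight per group, 896 in the 4 libraries alone and 1 to 903 with 1 library left out. For the difference of effects (10) it was 3 under quantile normalization, 18 and 20 with a raw value of 20 in at least 2 or all 8 samples, 3 with a single prior variance, 19 with 1 weight per group and 0 to 159 with 1 library left out. For culture time (325) it was 499, 166, 158 and 0 under quantile normalization, a single prior variance, 1 weight per group and the 4 libraries alone, and 1 to 674 with 1 library left out. Genes shared by both times (0) were 1 with a single prior variance and 0 to 6 with 1 library left out. A group left with 1 library is assumed to vary like the others, and fewer libraries leave less to estimate the spread from. That cannot account for the rise at 7 d without either unirradiated 12 h library. In this model the 7 d change of a gene does not use the 12 h libraries, which enter that contrast only through the shared spread. The unirradiated 12 h pair had the largest spread (SD of the difference 0.563). A smaller shared spread can thus account for that rise. The cause of the other moves was not tested. With the replicate number as a block, the difference of effects gave 4 genes, the 7 d contrast 564, culture time 388 and 12 h 0; the deviations of same-numbered libraries correlated at -0.018 to 0.297 over the 6 pairs of groups, highest between unirradiated 12 h and 7 d cells (0.148 for irradiation at 12 h, 0.036 at 7 d). The labels do not say that the numbers are pairs, and the main model did not take them as such.

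Of the 41 calls of lists, 6 held with an estimated correlation: 1 of 3 at 12 h, 3 of 15 at 7 d, 2 of 13 for the difference and 0 of 10 for culture time. The estimate was 0.0106 for p53 targets, near the preset 0.01, yet their camera adjusted p at 12 h moved from 7.85e-19 to 0.0254. For secretory factors it was -0.0035, yet their camera adjusted p over culture time moved from 2.41e-05 to 0.0634. This setting thus weakened calls also where the estimate hardly exceeded the preset. Other estimates lay far above it: 0.86 for ribosomal proteins, 0.80 for histones, 0.27 for extracellular matrix, 0.17 for Hippo components and 0.12 for TAZ/YAP targets. For such lists the adjusted p at the preset correlation is likely much too small. With 1 library left out the lists past the threshold ranged from 3 to 6, 13 to 15, 12 to 14 and 7 to 12, and from 39 to 43 in all. The direction turned without unirradiated 12 h replicate 2 for ribosomal proteins (adjusted p = 0.00945; range with 1 library left out 2.9e-06 to 0.989) and histones (1.32e-12; 8.8e-24 to 0.540) at 12 h, and without its replicate 1 for histones over culture time (0.193; from 6.27e-24). Over 227 named results and 3992 alternative values, 3296 kept their side of the threshold and direction, 651 lost the call, 45 gained it and 0 reversed. Of 1676 values for lists, 1592 kept both, 63 lost the call, 18 gained it and 3 reversed. With fry, calls ended for interferon genes at 12 h and for cilium genes over culture time. They also ended for ribosomal proteins and histones at 7 d, for the difference and over culture time. The other called lists kept their call with fry. Not run, because centred values hold neither counts nor levels: the count-based tests, other pseudocounts, and the planned filter on level. Depth is known only in relative terms, so no detection limit can be given.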

Other observations

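The tests of explanations in this part, and the groups for antigen presentation, clock, actin and small RNA genes, were chosen after the values were seen, and the counts of these groups are no independent evidence. The histone, DNA replication and TAZ/YAP lists and WWTR1 were fixed beforehand. Here too the SEs of medians are bootstraps over genes (2000 draws), which treat genes as independent and do not measure the spread between libraries. All 16 measured genes of antigen presentation had a positive change in irradiated cells at 7 d, with a median of 1.37 on the log2 scale. Of these, 8 rose and 0 fell by limma over all genes. The rest did not pass, HLA-DRA (0.45) and HLA-E (0.53) among them, and the group as a whole was not tested. HLA-B changed by 2.27, the immunoproteasome gene PSMB9 by 1.82, HLA-C by 1.74, the peptide transporter TAP1 by 1.59 and B2M by 1.48. At 12 h 0 of the 16 passed in limma, 9 had a positive change and the median was 0.06. Over culture time in unirradiated cells 4 of the 16 had a positive change, with a median of -0.39. HLA-C (-1.08) was the 1 that passed there. Lower 7 d controls may thus account for part of the change at 7 d. HLA genes share reads with each other, which leaves their single values uncertain.

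In unirradiated cells, some genes of the circadian clock were higher and some of the actin cytoskeleton lower at 7 d than at 12 h, with no test of either group as a whole. Of 16 clock genes 5 rose and 0 fell (median 0.81), namely TEF (1.97), PER1 (1.65), PER2 (1.33), CRY2 (1.25) and NR1D2. Of 15 actin and myosin genes 6 fell and 0 rose (median -0.91), among them ACTG1 (-1.65), CSRP1 (-1.34), TPM4 (-1.18), MYH9 (-1.17) and WDR1 (-1.10). In irradiated against unirradiated cells at 7 d, the clock genes BHLHE41 (1.90) and NR1D1 (1.61) rose, and the actin gene ACTB (-0.90) fell.

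Replication-dependent histones, whose transcripts normally lack poly(A) tails, differed between libraries in a pair of settings. Within the unirradiated 12 h pair they differed by a median of -1.79 (replicate 1 minus replicate 2), and 75 small nuclear and nucleolar RNAs, which also lack poly(A) tails, differed by -1.83 (SE 0.23). That is consistent with unequal carry-over of such RNA between these libraries. At 7 d the same small RNAs changed by -0.25 (SE 0.07) with irradiation while histones changed by -1.81, which argues against carry-over as the whole cause there. Over culture time in unirradiated cells the small RNAs changed by 0.83 and histones by 0.75. Both changes rested on unirradiated 12 h replicate 1, with medians of -1.25 for small RNAs and -0.76 for histones. Replicate 2 (0.37 and 1.03) lay near the unirradiated 7 d libraries (0.21 and 0.45 for small RNAs, 0.93 and 0.90 for histones). Carry-over stays open for that contrast, and a change with culture time is not shown by both 12 h libraries. Genes of DNA replication changed by a median of -0.54 (SE 0.05), so fewer replicating cells may contribute at 7 d, as a hypothesis that this table cannot separate from a change in histone RNA processing.

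Lower TAZ/YAP targets at 7 d were weighed against scaling and against the TAZ transcript. Under quantile normalization the list's median was -1.15 against -0.86 in the deposited scaling. The median difference per gene between these scalings had an SE of 0.10. Quantile normalization of centred values moved the 7 d calls towards decreases in general (220 higher and 344 lower, against 283 and 195). It therefore cannot decide whether scaling contributed. In the deposited scaling the median 7 d change over all genes was 0.03, so the list was low relative to the median gene. WWTR1 changed by -0.26 (95% interval -0.65 to 0.13), an interval that holds both no change and a decrease, so a lower WWTR1 transcript cannot be told apart from regulation of the protein, which was not measured. CTGF and CYR61 also fell with culture time in unirradiated cells. That lowers the 7 d controls, so it argues against a change in the controls as the cause. The list's medians were -0.23 and -0.22 in the unirradiated 7 d libraries, and -1.10 and -0.88 in the irradiated ones. Density was not measured, so a difference in density between irradiated and unirradiated cultures stays untested.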
